A study of Homo sapiens with 6 samples.

How the data were processed

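Total RNA of 6 samples of human endometrial stromal cells was measured on single-colour expression arrays, 3 per group. Per the labels, cells were grown in medium with 5% serum and treated in medium with 2% stripped serum, transfected for 48 h, and given the differentiation cocktail for 24 h. The labels describe 1 siControl and 1 siESR1 array from each numbered culture sample, and this was read as the same culture and taken to pair the arrays. How many siRNA sequences were used is not given in the sources used here. Nothing in the sources used here says whether each culture came from a different donor.

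The deposited values are log2 signals per probe set or transcript cluster, already normalized and summarised by the authors. Per the submitters' processing notes, MAS5, Affymetrix Expression Console 1 and RMA were used, with no record of which was applied to which array. A linear signal had been planned for the culture 1 table. Its values ran from 2.51 to 14.7 with medians of 6.67 and 6.70, so they were taken as log2, and the planned scaling to a common median and the floor at the 20th percentile were applied on that scale. Medians were closer within a culture than between cultures 2 and 3 (5.96 and 5.97 against 6.08 and 6.09). The 75th percentiles showed no such gap, with 7.73 and 7.72 in culture 2 and 7.75 and 7.77 in culture 3. Levels were tested only within the table of cultures 2 and 3. Culture 1, from the other table, entered a test only as its within-culture difference, in the fit over 3 cultures. In the siControl array of culture 3, 52.5% of clusters shared their value with another cluster of that array, against 8.81% in culture 2. Small differences were still recorded there: IFI6 differed by 0.0027 between the arrays of culture 3. The step that made values recur is not known from the sources used here. Arrays give no counting depth, and no detection calls were used.

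Probes were named through the platform annotation. Of 22277 probe sets, 19070 had 1 gene symbol, 1043 several and 2164 were unlisted. Of 33297 clusters, 19460 had 1 symbol, 1754 several and 12083 were unlisted. Probes with several symbols named no gene, and HOXA10 had no probe that could be used. One probe stood for each gene, the one with the highest mean, and genes with a mean under the 25th percentile of all probes of their table were left out. This left 15999 genes in the table of cultures 2 and 3, 9563 in that of culture 1, and 8982 in both.

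Differences were siESR1 minus siControl. The planned test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend) on the 4 arrays of cultures 2 and 3 with no block, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Because groups share culture numbers, the same fit with culture as a block, and limma on the within-culture differences of 3 cultures against 0, were planned as alternatives. Deviations from the group means correlated at 0.84 between the arrays of 1 culture and at -0.84 between crossed arrays. With 2 arrays per group these values mirror each other by construction, and the check covers only cultures 2 and 3. The 2 fits are printed side by side, since the block changed the calls. The block fit has 1 residual degree of freedom per gene before the variances are moderated across genes. Of the genes tested, 55.5% were tied in culture 3, and these entered the moderation too. A tie was an exact equality of the deposited values.

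The design named 26 gene lists before the data were examined. They were tested with camera in limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. With an estimated correlation, camera is limited to the residual degrees of freedom of the fit, which are few here. A low adjusted p was then nearly out of reach for any list, so a call lost there does not show that correlated genes made it. List medians per culture were also ranked among 10000 random lists matched on mean expression. Named genes were chosen by a rule set at the same time: ESR1, up to 12 genes per direction past the test and of 1 sign in cultures 2 and 3, filled up with genes at least 1.5-fold and of 1 sign in all 3 cultures, the 4 members of each list with the largest absolute mean difference, and PRL, IGFBP1, FOXO1, WNT4, PGR, BMP2, HAND2, HOXA10 and MED1. No gene passed without the block, so all 19 genes of the first kind were filled in. Genes without an official symbol, Y-linked genes, XIST, and histone, immunoglobulin, olfactory receptor and small nucleolar RNA families were left out. All 121 genes the rule gave are named in addition to ESR1. Which of them are described at length, and in which part of the text, was chosen after their values were seen.

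The fits were tested on simulated data made from the real culture means and moderated spreads, in 20 runs with 200 genes changed by 0.5, 1 or 1.5 log2. For the table of cultures 2 and 3 (15999 genes) the block fit recovered 91.1% of the genes changed by 0.5 and 100% of those changed by 1 or 1.5, and 11.8% of its calls were false, above the nominal level. The fit without the block recovered 0% at each size. The fit over 3 cultures (8982 genes) recovered 99.6%, 100% and 100%, with 7.52% of calls false. With no change simulated, 0 genes were 1.5-fold apart in 1 direction in 3 cultures. A list of 24 genes shifted by 0.5 was called in 20 of 20 runs with and without the block. Of 2000 unshifted lists, 15 passed an unadjusted p of 0.05 without the block and 0 with it. Simulated genes varied independently and held no ties. The real genes held many ties, and the estimated correlation in the mitosis list was 0.90 in the fit without the block. These rates therefore need not hold for the real lists and fits.

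Alternatives covered the filter (none, 50th percentile), the mean of a gene's probes, renormalization by quantiles or by the median, the eBayes trend, each array or culture left out, the floor (none, 40th percentile), and the fold (1.2 and 2). Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.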

Results

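Gene expression was measured in primary human endometrial stromal cells, the fibroblasts of the uterine lining that differentiate into decidual cells under ovarian steroids. The cells were transfected for 48 h with a nontargeting siRNA (siControl) or an siRNA against ESR1, which encodes estrogen receptor alpha (siESR1), and then exposed for 24 h to estrogen, progesterone and a cAMP analog. Each of 3 cultures gave 1 siControl and 1 siESR1 array, 6 arrays in all. Culture 1 was hybridised to an array with 22277 probe sets, and cultures 2 and 3 to another array with 33297 transcript clusters. The number of arrays limits the precision of every value given here. In culture 3 the siControl and siESR1 values were exactly equal for 17736 clusters (53.3%), against 19 clusters in culture 2 and 818 probe sets (3.67%) in culture 1. A gene tied in culture 3 was therefore not read as unchanged. Its difference of 0.00 still entered the means, fits, list medians and correlations as a value, unless the tied genes are said to be left out.

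The targeted transcript was examined first. In culture 2 the ESR1 log2 signal was 6.27 with siControl and 6.02 with siESR1, and in culture 3 it was 5.60 in both arrays, an exact tie. A further ESR1 cluster read 4.90 and 4.97 in culture 2, and 4.95 in both arrays of culture 3. Over cultures 2 and 3 the mean difference, siESR1 minus siControl, was -0.12 (SE 0.29 without culture as a block and 0.11 with it, n = 2 per group). Both this mean and the mean over 3 cultures below count the tie as no difference. The limma adjusted p was 0.76 with culture as a block, and the unadjusted limma p without it was 0.69. In culture 1 the 9 ESR1 probe sets disagreed: the brightest read 6.18 and 6.14, and the differences ran from -0.87, in a probe set that read 4.51 and 3.64, to 0.26. The probe set at -0.87 was also taken for culture 1, a choice made after its value was seen, with neither the filter nor the floor applied to it. The mean over 3 cultures was then -0.38 with an adjusted p of 0.22. The siESR1 reading of that probe set, 3.64, lay near the 10th percentile of its array (3.58). In culture 2 the brighter ESR1 cluster differed by -0.25 and the other was not lower. The SD of the differences over all genes tested in that culture was also 0.25. Most culture 1 probe sets were lower with siESR1, but apart from the one at -0.87 the lowest was -0.22. The SD over genes was 0.19 there. ESR1 is therefore a weak check of the labels in cultures 1 and 2. The tie in culture 3 left its knockdown unmeasured, so ESR1 cannot check the labels of that culture. Across 8982 genes its differences correlated with those of cultures 1 and 2 (Pearson r = 0.504 and 0.453). This argues against labels exchanged in culture 3 alone.

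**Figure D1:**
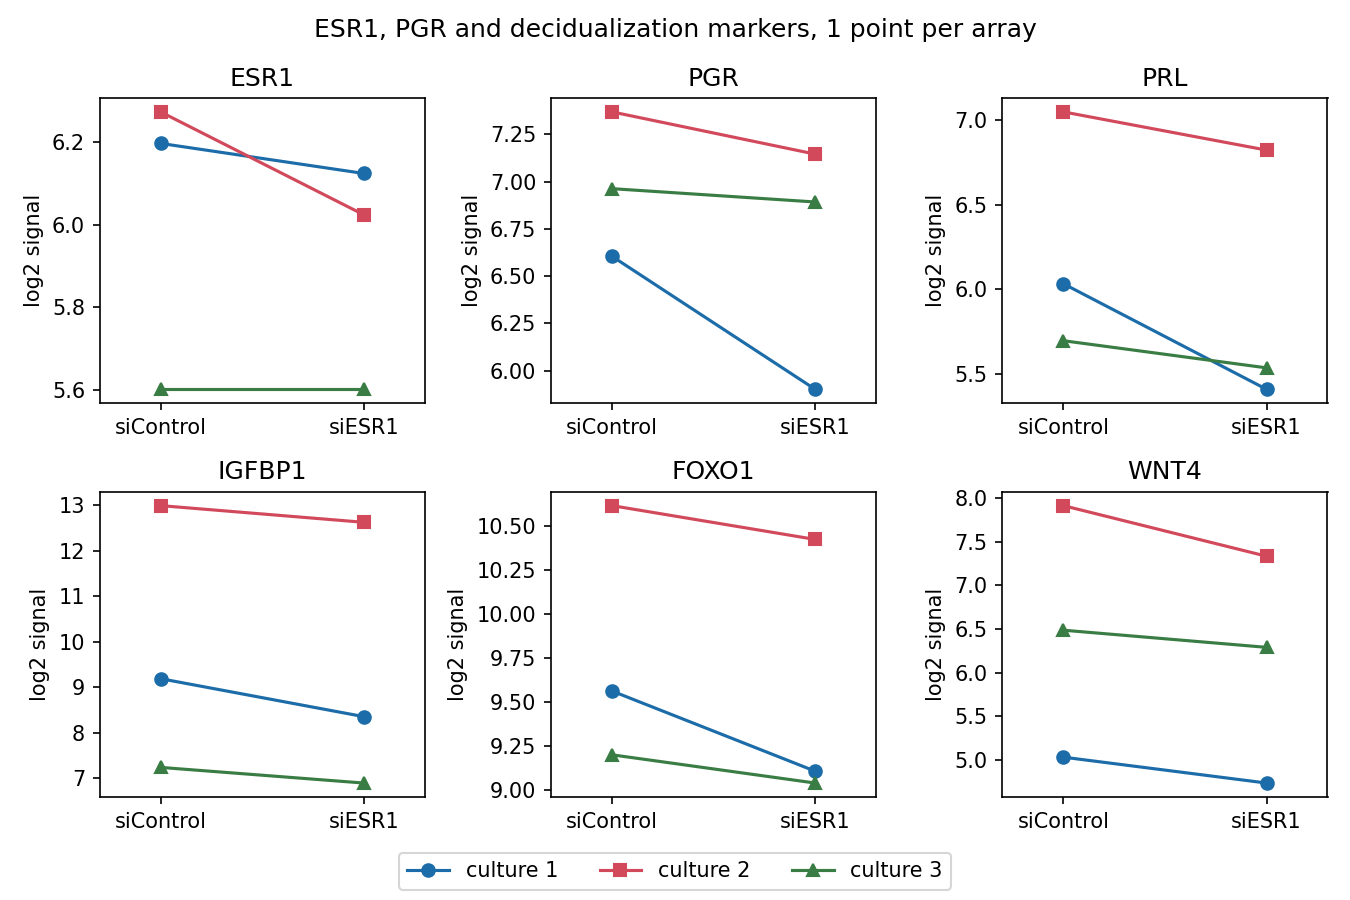
Log2 signal of ESR1, PGR, PRL, IGFBP1, FOXO1 and WNT4 on each of the 6 arrays (y axis, log2, a separate range per gene), with a line joining siControl and siESR1 of 1 culture. The 2 arrays of culture 1 come from another platform and are drawn after scaling to a common median, so levels compare only along a line. IGFBP1 lay lower with siESR1 on all 3 lines, by 0.83, 0.37 and 0.34, while ESR1 was level at 5.60 in culture 3.

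The main question was which genes changed when ESR1 was targeted during differentiation. In siESR1 cells MET, the hepatocyte growth factor receptor, and TNFSF4, a ligand of the tumor necrosis factor family, were higher, and OSGIN2 and TIMP3, an inhibitor of metalloproteinases, were lower. MET stood 2.30-fold higher (SE of the log2 difference 0.11 with culture as a block, 0.80 without) and TNFSF4 2.21-fold (1.14 log2, SE 0.11 and 0.90). OSGIN2 was 2.08-fold lower (-1.06, SE 0.10 and 0.62) and TIMP3 2.00-fold lower (SE 0.12 and 0.16). Of 15999 genes tested in cultures 2 and 3 (n = 2 per group), 0 passed an adjusted p of 0.05 in limma without the culture in the model. At an unadjusted p under 0.05 there were 170, fewer than this threshold would give on average among 15999 unchanged genes. A plain test per gene also called 0. The labels give the same culture number to both groups. With culture as a block, 240 genes passed, of which 141 rose and 99 fell. Leaving out the genes tied in culture 3 lowered this count from 240 to 30, all 30 of them among the 240. Quantile normalization of the 4 arrays raised the count to 514. None of the 240 was tied in culture 3. In culture 1, which took no part in that fit, 172 of the 240 were measured and 167 (97.1%) had the same sign. Of all 8982 genes on both platforms, 62.7% did.

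A fit to the within-culture differences of all 3 cultures (n = 3) called 328 of the 8982 genes, 173 higher and 155 lower. It shared 147 with the 240. Without culture 1 the count was 516, and without culture 3 it was 115. The genes named as changed below passed in the block fit unless another fit is given. None was called without the block. Of the 41 genes named by the rule that passed in the block fit, 16 still passed when the genes tied in culture 3 were left out: 11 of those alike in 3 cultures, and CDC20, CDK1, BUB1B, CLDN1 and CNN1. Over 3 cultures 38 of the 41 were measured and 35 passed, and ADAMTS1, IGF1 and CLDN11 did not. In culture 1 the difference had the other sign than the mean of cultures 2 and 3 for 16 genes named by the rule: LRP5, TGFB1, INHBA, FOSB, CXCL1, CYP1B1, PGK1, ASNS, MVD, CLDN11, MUC1, KDR, CD14, GNLY, NCAM1 and HAND2.

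At a difference of at least 1.5-fold in 1 direction in each of the 3 cultures, 19 genes were found, 7 higher and 12 lower. No gene met this rule when the sign of any 1 culture was turned. At 1.2-fold the count was 239, and at 2-fold MET alone was left. The 7 higher genes were MET, TNFSF4, RAB27B, a GTPase of vesicle secretion, SYT1, a calcium sensor of vesicle fusion, LMNB2 of the nuclear lamina, PMAIP1, a BH3-only protein of apoptosis, and TNC, the matrix protein tenascin C. MET differed by 1.42, 1.03 and 1.37 in cultures 1, 2 and 3 (adjusted p = 0.0024 in the block fit and 0.0033 over 3 cultures). RAB27B differed by 0.66, 0.91 and 0.98, and PMAIP1 by 0.69, 0.86 and 0.60. SYT1, LMNB2 and TNC had mean differences of 0.75, 0.73 and 0.71 in cultures 2 and 3.

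The 12 lower genes were OSGIN2, TIMP3, TAF13, a subunit of the general transcription factor TFIID, CAMK2N1, an inhibitor of a calmodulin-dependent kinase, TPCN1, an endolysosomal ion channel, PIGK, an enzyme of GPI anchor attachment, ABCA1, a cholesterol exporter, ADH1B, an alcohol dehydrogenase, HYOU1, a chaperone of the endoplasmic reticulum, GPX7, a peroxidase of the same compartment, CLN8, and KAT2B, a histone acetyltransferase. TAF13 differed by -1.36, -1.22 and -0.83 in cultures 1, 2 and 3 (adjusted p = 0.0056 in the block fit). CAMK2N1 differed by -1.22, -0.85 and -1.02, and TIMP3 by -1.18, -1.19 and -0.81. ADH1B differed by -0.79, -0.76 and -0.77, and its 2 other probe sets in culture 1 by -1.50 and -0.29. HYOU1 differed by -0.75, -0.81 and -0.71, and ABCA1 by -0.66, -0.75 and -0.80. The mean differences of TPCN1, PIGK, GPX7, CLN8 and KAT2B in cultures 2 and 3 were -0.89, -0.88, -0.73, -0.70 and -0.66. All 19 genes passed both the block fit (adjusted p from 0.0024 to 0.014) and the fit over 3 cultures. Both fits test the same differences that chose the genes, so passing them adds no separate support. Culture 1 held 17 other probe sets for 10 of the 19, and 15 of the 17 had the same sign. The others were 1 of MET, which was tied, and 1 of OSGIN2, at 0.14. Without the genes tied in culture 3 the block fit kept 11 of them and lost 8: SYT1, LMNB2, PMAIP1, TNC, PIGK, GPX7, CLN8 and KAT2B (adjusted p from 0.052 to 0.059).

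**Figure D2:**
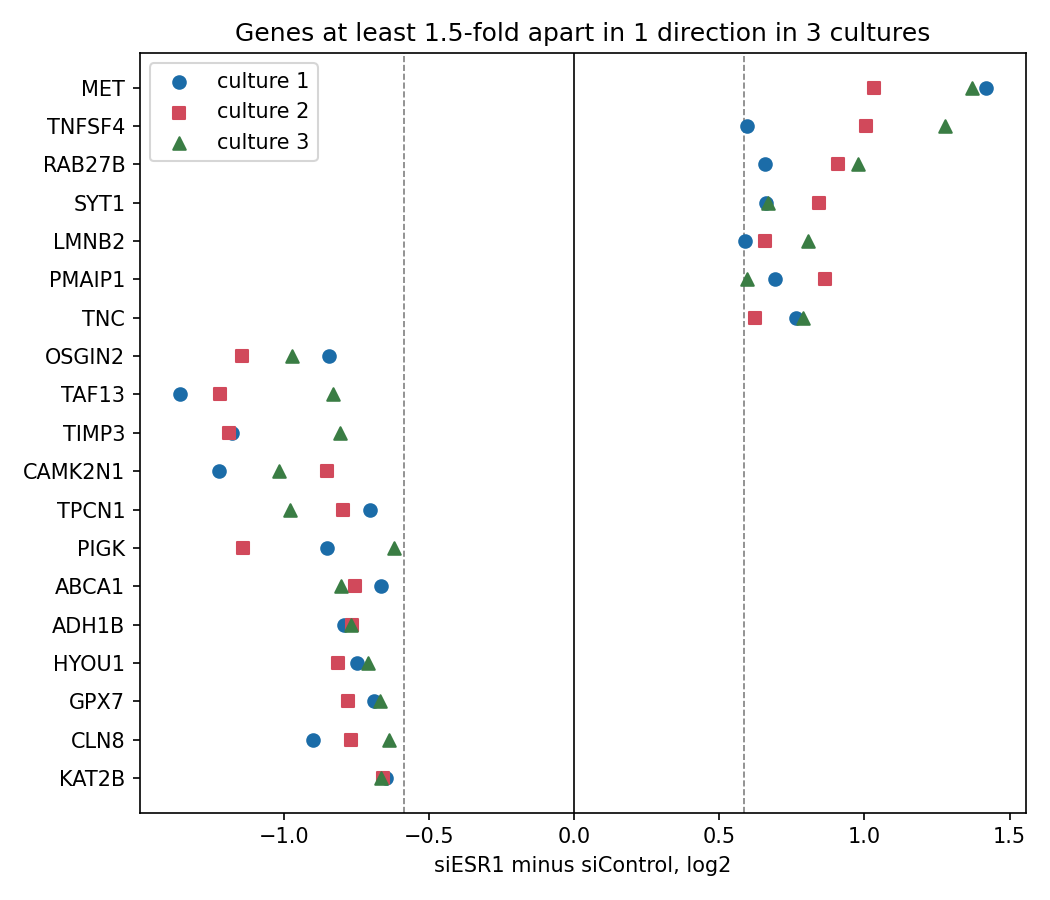
Difference in log2 signal, siESR1 minus siControl (x axis), of the 19 genes at least 1.5-fold apart in 1 direction in all 3 cultures, with 1 symbol per culture. Dashed lines mark 1.5-fold. MET reaches 1.42 in culture 1 and TAF13 -1.36.

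Across the 8982 genes on both platforms, the culture 1 differences correlated with the mean differences of cultures 2 and 3 (Pearson r = 0.504, Spearman rho = 0.413). The value is across genes, which are not independent replicates, and has no p. No array entered both sides. Single cultures gave r = 0.381 between cultures 1 and 2, 0.504 between 1 and 3, and 0.453 between 2 and 3.

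**Figure D3:**
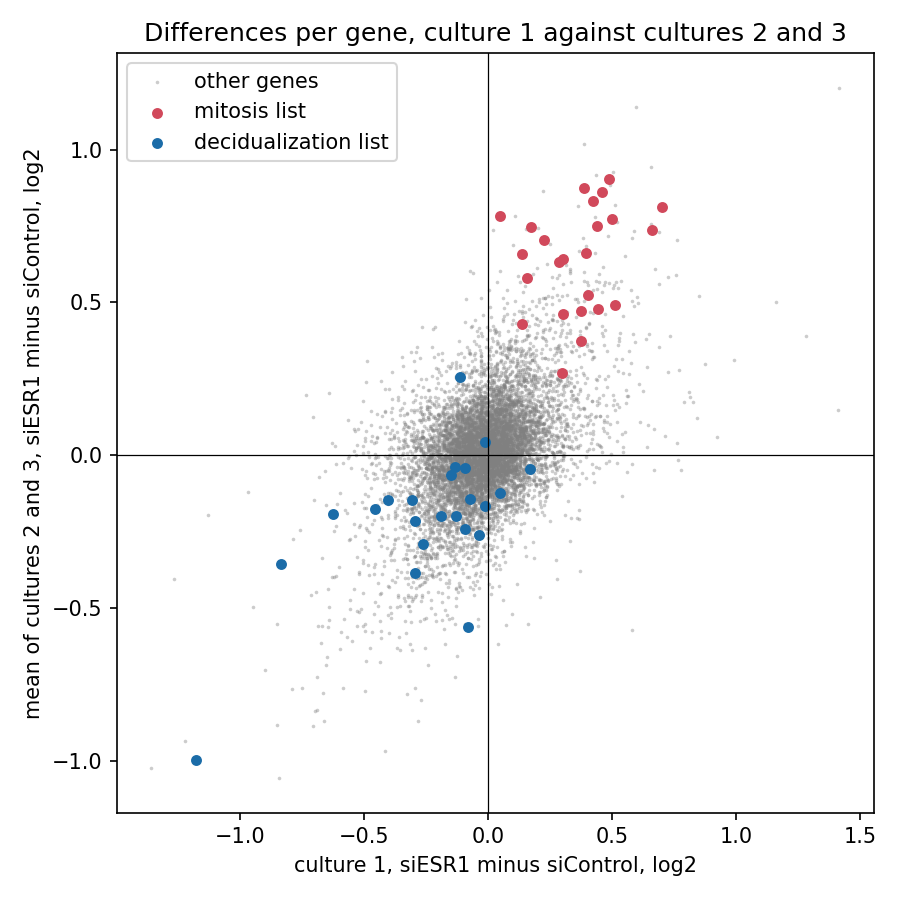
Difference in log2 signal, siESR1 minus siControl, in culture 1 (x axis) against the mean difference of cultures 2 and 3 (y axis), 1 point per gene for 8978 genes. Members of the mitosis list are red and lie above 0 on both axes, and members of the decidualization list are blue and lie mostly below 0, with TIMP3 at -1.18 on the x axis.

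Genes of mitosis were higher in siESR1 cells. All 24 members of the mitosis list on both platforms were above 0 in each of the 3 cultures, with list medians of 0.37, 0.49 and 0.76. In the block fit 16 of 24 rose, 0 fell and 8 did not pass, and 24 passed when adjusted over the list alone. Without the genes tied in culture 3, none of which was a member, 4 of 24 passed. CDC20, an activator of the anaphase-promoting complex, rose by 0.91 on the log2 scale (1.87-fold, SE 0.10, adjusted p = 0.0056). The cyclin-dependent kinase CDK1 rose by 0.86 (1.81-fold, adjusted p = 0.0084), the spindle factor TPX2 by 0.87 (1.83-fold, adjusted p = 0.012, and 0.055 without the tied genes) and the checkpoint kinase BUB1B by 0.83 (1.78-fold, adjusted p = 0.0071). Without the block no member passed, and the list stood above other genes in camera with an adjusted p of 7.7e-26. With an estimated correlation between genes (0.90 for this list without the block) the camera adjusted p was 0.48, and 0.57 in the block fit. The 0.90 also reflects the difference between cultures 2 and 3, which the fit without the block leaves in its residuals. Few residual degrees of freedom keep camera with an estimated correlation from deciding, so the correlation between members remains a limit on the call. With fry the adjusted p of this list was 0.65 without the block and 0.27 with it. Genes of DNA replication had medians of 0.28, 0.12 and 0.30 in cultures 1, 2 and 3. Of 23 tested, 3 rose, 0 fell and 20 did not pass, and 5 passed when adjusted over the list alone. The 3 were GINS1 and GINS2, subunits of the replicative helicase, at 0.72 and 0.51, and CCNE2, a cyclin of S phase entry, at 0.59 (adjusted p = 0.014, 0.039 and 0.027 in the block fit). Without the tied genes 0 of 20 passed, with adjusted p values of 0.055, 0.076 and 0.070 for GINS1, GINS2 and CCNE2. RRM1, a subunit of ribonucleotide reductase, differed by 0.44 (adjusted p = 0.099 in the block fit and 0.048 over 3 cultures). The camera adjusted p was 3.7e-05 (adjusted p = 0.69 with an estimated correlation).

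Of the genes of decidualization TIMP3 was lower in siESR1 cells, and most members did not pass. The list medians were -0.14, -0.15 and -0.17 in cultures 1, 2 and 3. Of 28 members tested, TIMP3 fell and 27 did not pass in the block fit, and 5 passed as lower when adjusted over the list alone. Camera gave an adjusted p of 6.7e-05 without the block (adjusted p = 0.65 with an estimated correlation). IGFBP1, an insulin-like growth factor binding protein secreted by decidual cells, differed by -0.83, -0.37 and -0.34 in cultures 1, 2 and 3 (adjusted p = 0.13 in the block fit and 0.035 over 3 cultures). PRL, the decidual hormone prolactin, differed by -0.62, -0.23 and -0.16 (adjusted p = 0.55 and 0.11). FOXO1, a transcription factor of decidualization, differed by -0.45, -0.19 and -0.16 (adjusted p = 0.60 and 0.12), and WNT4 by -0.30, -0.58 and -0.20 (adjusted p = 0.17 and 0.064). RORB, an orphan nuclear receptor, differed by -0.56 and SOD2, a mitochondrial superoxide dismutase, by -0.43 over cultures 2 and 3 (adjusted p = 0.14 and 0.096 in the block fit). BMP2 differed by -0.31, 0.08 and -0.38, and HAND2 by 0.05, -0.07 and -0.18. HOXA10 was not analysed here. The level of IGFBP1 differed far more between cultures: with siControl it was 53.9-fold higher in culture 2 than in culture 3.

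Among nuclear receptors and their coregulators, 0 of 13 tested members passed in either direction, and 6 of the 13 were tied in culture 3. PGR, the progesterone receptor, differed by -0.70, -0.22 and -0.07 (adjusted p = 0.70 in the block fit and 0.18 over 3 cultures). MED1, a Mediator subunit that binds nuclear receptors, differed by 0.05, 0.33 and 0.30 (adjusted p = 0.19 and 0.18). The retinoic acid receptor RARB and the glucocorticoid receptor NR3C1 differed by 0.24 and 0.18 over cultures 2 and 3 (adjusted p = 0.39 and 0.61 in the block fit). Targets of the estrogen and progesterone receptors had a median difference of -0.11 over 20 members, of which 2 fell and 18 did not pass, with 4 past the test when adjusted over the list alone. The chemokine CXCL12 fell by 0.76 (adjusted p = 0.011) and the growth factor IGF1 by 0.52 (adjusted p = 0.047). IGF1 did not pass over 3 cultures (adjusted p = 0.063) or without the tied genes (adjusted p = 0.089), and CXCL12 passed over 3 cultures (adjusted p = 0.023) but not without the tied genes (adjusted p = 0.051). The interleukin receptor IL1R1 differed by -0.42, -0.40 and -1.54 in cultures 1, 2 and 3 (adjusted p = 0.053 in the block fit), and IRS2, an adaptor of insulin signalling, by -0.27, -0.54 and -0.26 (adjusted p = 0.12). Camera gave this list an adjusted p of 2.0e-04 (adjusted p = 0.38 with an estimated correlation).

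Several matrix proteases and inhibitors and 2 collagens were lower in siESR1 cells, while most members of both lists did not pass. Of 19 proteases and inhibitors tested, 6 fell, 0 rose and 13 did not pass, with list medians of -0.17, -0.31 and -0.32 in cultures 1, 2 and 3. When adjusted over the list alone, 11 were lower and 3 higher. The 3, named after their values were seen, were the collagenase MMP1 and the plasminogen activators PLAT and PLAU, which were above 0 in every culture, MMP1 by 0.69, 0.25 and 0.87 (adjusted p = 0.091 in the block fit and 0.030 over 3 cultures). Besides TIMP3, the genes past the test over all genes included MMP11, a metalloproteinase, which fell by 0.78 (1.72-fold, adjusted p = 0.011), ADAMTS1, a further metalloproteinase, by 0.73 (adjusted p = 0.012, and 0.051 over 3 cultures, with -0.13 in culture 1), and SERPINE2, a serine protease inhibitor, by 0.69 (adjusted p = 0.028). Without the tied genes TIMP3 alone passed of 17 members. Of 25 extracellular matrix genes, COL1A1 and COL4A1, which encode collagen chains, fell by 0.59 and 0.50 (adjusted p = 0.023 and 0.043, and 0.066 and 0.081 without the tied genes), TNC rose, and 22 did not pass, among them COL6A3, a chain of collagen VI (-0.38, adjusted p = 0.13). Adjusted over the list alone, 7 were lower and 1 was higher. The camera adjusted p was 1.0e-07 for the proteases and 7.0e-07 for the matrix list (adjusted p = 0.38 for both with an estimated correlation).

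Stromal fibroblast markers had a median difference of -0.20 over 14 members. COL1A1, which the matrix list also holds, fell, and 13 did not pass, with 2 lower when adjusted over the list alone. The receptor PDGFRA differed by -0.45 and the fibroblast protease FAP by -0.33 (adjusted p = 0.10 and 0.25 in the block fit), and S100A4, a calcium-binding protein of fibroblasts, by -0.33 (adjusted p = 0.32). Camera gave an adjusted p of 3.7e-05 (adjusted p = 0.38 with an estimated correlation). Genes of the unfolded protein response had a median of -0.16 over 20 members, and 0 passed in the block fit. Adjusted over the list alone, 3 were lower and 1 was higher. The chaperones DNAJB9 and SDF2L1 differed by -0.42 and -0.43, while PDIA4, a protein disulfide isomerase, differed by 0.34 (adjusted p = 0.14, 0.16 and 0.17 in the block fit). Over 3 cultures DNAJB9 and PDIA4 passed, in opposite directions (adjusted p = 0.048 and 0.047), and SDF2L1 did not (adjusted p = 0.076). ASNS, asparagine synthetase, differed by -0.46 in cultures 2 and 3 (adjusted p = 0.053) and by 0.21 in culture 1. The camera adjusted p was 0.0019 (adjusted p = 0.38 with an estimated correlation).

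**Figure D4:**
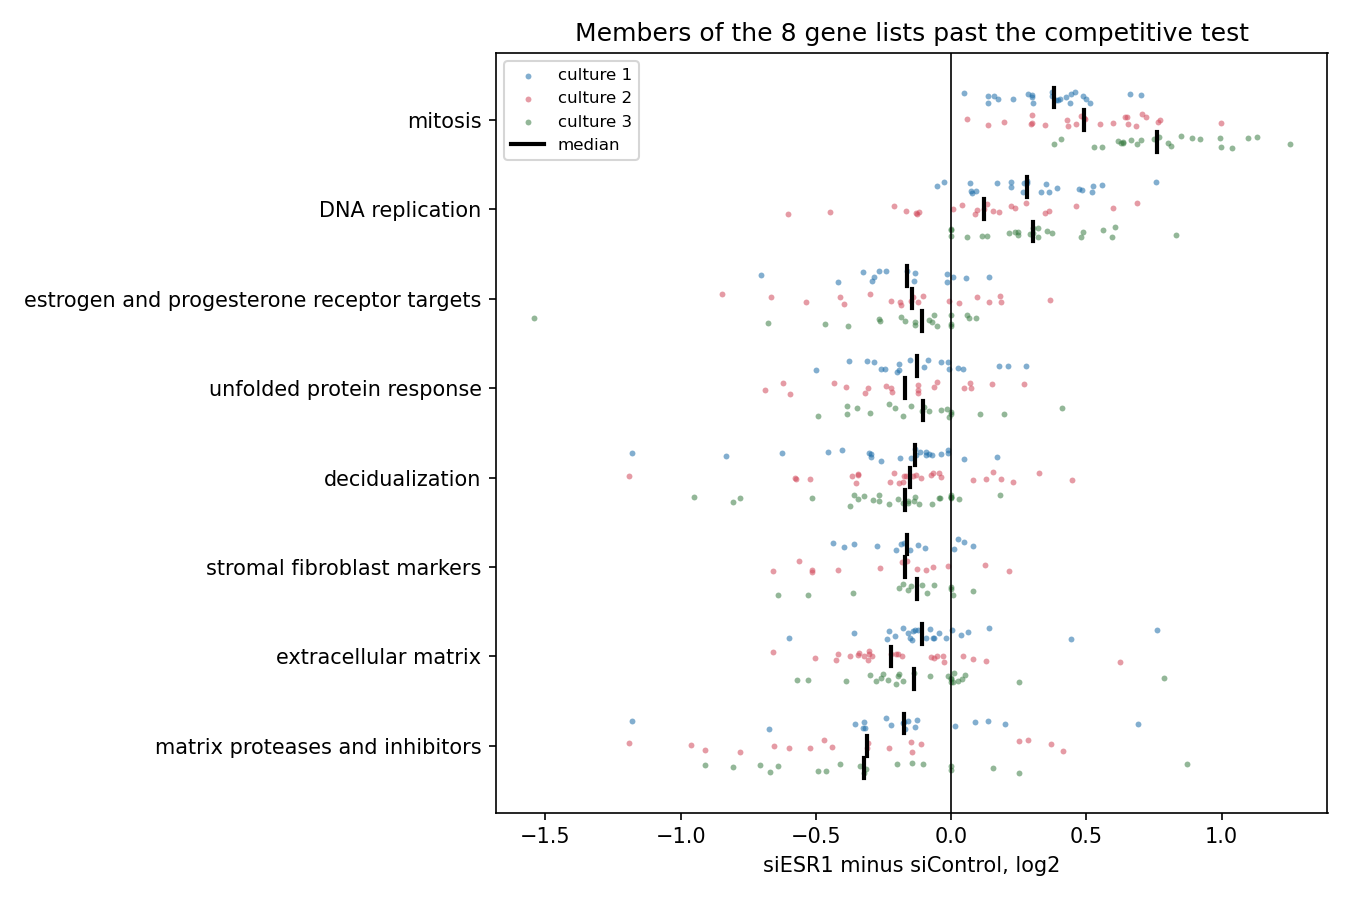
Difference in log2 signal, siESR1 minus siControl (x axis), of each member of the 8 lists past camera in cultures 2 and 3, with 1 point per gene and culture and a black bar at the median of the members drawn. Points are spread vertically for clarity. The mitosis medians of cultures 2 and 3 are 0.49 and 0.76, and those of the proteases and inhibitors are -0.31 and -0.32.

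Of the 26 lists, 8 passed camera without the block, 2 higher and 6 lower. With the block 12 passed, 3 higher and 9 lower, and over 3 cultures 9. The 4 lists added by the block were interferon response, higher (adjusted p = 0.030), and retinoid pathway, growth factors and vessel signals, and glycolysis and hypoxia, lower (adjusted p = 0.027, 0.035 and 0.043). Few members passed in the block fit: 1 of 17 rose in the interferon list, and 1 of 15 retinoid and 1 of 22 glycolysis genes fell. Of 22 growth factors and vessel signals 2 fell and 1, VEGFC, rose. Medians in cultures 1, 2 and 3 were 0.12, 0.04 and 0.19 for interferon and -0.24, 0.0015 and 0 for retinoid genes. For growth factors they were -0.12, -0.07 and -0.02, and for glycolysis -0.04, -0.04 and 0. Over 3 cultures the retinoid list kept its call (adjusted p = 0.015), and the interferon, growth factor and glycolysis lists lost theirs (adjusted p = 0.058, 0.082 and 0.068). With an estimated correlation the adjusted p of these 4 was 0.71, 0.64, 0.57 and 0.57 in the block fit, and no list of the 26 passed. Without the block that version, with few residual degrees of freedom, also lost the stromal fibroblast list (adjusted p = 0.38). The estimated correlation of that list was -0.065 there, below the preset 0.01. The losses without the block therefore cannot be put down to gene correlation alone. With fry no list of the 26 passed, either with or without the block. The lowest fry adjusted p was 0.14 without the block, for the stromal fibroblast and glycolysis lists. With the block it was 0.13, for BMP, activin and TGF-beta signalling. In the retinoid list STRA6, a retinol transporter, fell by 0.58 (adjusted p = 0.035), and CRABP2, a retinoic acid binding protein, differed by -0.48 (adjusted p = 0.063 in the block fit and 0.020 over 3 cultures). The retinol dehydrogenase RDH10 and the retinal reductase DHRS3 differed by -0.49 and -0.29 (adjusted p = 0.31 and 0.50 in the block fit). Among growth factors, IGFBP3, a carrier of insulin-like growth factors, differed by -0.54 (adjusted p = 0.053 in the block fit and 0.043 over 3 cultures), and VEGFA, an angiogenic factor, by -0.50 (adjusted p = 0.13). BNIP3, a mitochondrial protein induced by hypoxia, fell by 0.50 (adjusted p = 0.046), while the glycolytic enzymes HK2 and PGK1 differed by -0.34 and 0.23 (adjusted p = 0.27 and 0.49). Of the interferon-induced genes, OAS2, IRF9 and MX1 differed by 0.47, 0.35 and 0.23 (adjusted p = 0.076, 0.25 and 0.57).

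In the signalling lists 0 genes passed in the block fit, and many members were tied in culture 3. Tied were 13 of 23 WNT genes, 10 of 22 BMP, activin and TGF-beta genes, 8 of 18 cAMP and CREB targets and 7 of 16 p53 targets. WNT2, a secreted ligand, LRP5, a coreceptor, and LEF1, a transcription factor of the WNT pathway, differed by -0.34, -0.33 and 0.23 (adjusted p = 0.20, 0.20 and 0.42). The ligands TGFB1, BMP4 and INHBA differed by -0.43, -0.36 and -0.32 (adjusted p = 0.12, 0.18 and 0.22). Of the cAMP and CREB targets, the phosphodiesterase PDE10A, the phosphatase DUSP1 and the transcription factor NR4A2 differed by -0.33, -0.30 and -0.26 (adjusted p = 0.27, 0.32 and 0.64). FOSB, a further transcription factor, differed by 0.36 in culture 2 and was tied in culture 3 (adjusted p = 0.66). NR4A2 differed in sign between cultures 2 and 3 (0.13 and -0.66). Among p53 targets, the RNA-binding protein ZMAT3, the stress cytokine GDF15 and the oxidoreductase TP53I3 differed by 0.34, -0.22 and 0.13 (adjusted p = 0.16, 0.47 and 0.75). The repair factor DDB2 differed by 0.32 and 0.51 in cultures 1 and 2 and was tied in culture 3 (adjusted p = 0.54). The lists of WNT signalling, of BMP, activin and TGF-beta signalling, of cAMP and CREB targets and of p53 targets had camera adjusted p values of 0.099, 0.75, 0.28 and 0.26 without the block.

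The chemokines CCL7, CCL8 and CXCL1 differed by -0.54, -0.49 and -0.36 in culture 2, and all 3 were tied in culture 3 (adjusted p = 0.51, 0.55 and 0.66 in the block fit). The estrogen hydroxylase CYP1B1 and the steroid sulfatase STS differed by -0.34 and 0.29 over cultures 2 and 3 (adjusted p = 0.16 and 0.46), and CYP1B1 by 0.27 in culture 1 (adjusted p = 0.61 over 3 cultures). In cholesterol synthesis and transport, STARD4, HMGCS1, SC5D and MVD differed by 0.36, 0.30, -0.29 and -0.24 (adjusted p = 0.18, 0.26, 0.25 and 0.39). JUP, the junction protein plakoglobin, differed by -0.64, -0.29 and -0.71 in cultures 1, 2 and 3 (adjusted p = 0.079 in the block fit and 0.022 over 3 cultures), and the cadherin CDH2 by 0.15, 0.25 and 0.50 (adjusted p = 0.14 and 0.095). The lists of inflammatory cytokines and chemokines, of prostaglandin and steroid enzymes, of cholesterol synthesis and of gap and adherens junctions had camera adjusted p values of 0.92, 0.69, 0.70 and 0.92 without the block, and nuclear receptors and coregulators 0.77. In the inflammatory list 15 of 20 members were tied in culture 3, the median and mean were slightly above 0, and the test pointed down. Median and mean differed in sign for the junction and leukocyte lists.

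Markers of other cell types did not pass camera as lists. Many were tied in culture 3, where no tied gene was called in the block fit. Tied were 8 of 12 epithelial, 6 of 8 endothelial, 7 of 10 leukocyte and 5 of 12 perivascular and smooth muscle markers. The counts below are thus not a measured absence of change. Of epithelial markers 0 of 12 passed in the block fit: SPP1, a secreted phosphoprotein, the keratin KRT8 and the mucin MUC1 differed by -0.27, 0.18 and 0.14, and the transcription factor ELF3 differed by 0.29 in culture 2 and was tied in culture 3. Of endothelial markers 0 of 8 passed, with the receptors TEK and TIE1 at -0.32 and -0.21. The adhesion molecule ESAM differed by -0.31 in culture 2 and was tied in culture 3. KDR, a VEGF receptor, differed by 0.31 in culture 2, was tied in culture 3 and differed by -0.39 in culture 1. Of leukocyte markers 1 of 10 passed, the macrophage marker CD68, at -0.47 and -1.11 in cultures 2 and 3 (adjusted p = 0.028 in the block fit). The monocyte marker CD14 differed by -0.16 in cultures 2 and 3 and by 0.16 in culture 1. GNLY, a protein of cytotoxic granules, differed by -0.20 and 0.24 in cultures 1 and 2 and was tied in culture 3, and NCAM1, an adhesion molecule of uterine natural killer cells, by -0.34 in culture 1 and by 0.05 and 0.15 in cultures 2 and 3. Of perivascular and smooth muscle markers 1 of 12 passed, CNN1, at 0.50, 0.97 and 0.88 in cultures 1, 2 and 3 (adjusted p = 0.0049 in the block fit). Adjusted over the list alone, 4 were higher, and the smooth muscle proteins ACTG2 and TAGLN differed by 0.66 and 0.35 (adjusted p = 0.13 and 0.20). The camera adjusted p values of these 4 lists without the block were 0.92, 0.40, 0.39 and 0.21. Of 11 housekeeping genes 0 passed (camera adjusted p = 0.92), with TFRC, TBP, PPIA and B2M at -0.30, 0.27, 0.22 and -0.22.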

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

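Fits without the genes tied in culture 3, fits over 3 cultures with 1 left out, block fits after rescaling and the ESR1 value from another probe set were chosen after seeing the data. With the replicate block over cultures 2 and 3 the count of genes changed went from 0 to 240, and with the replicate block over 3 cultures to 328. Without the tied genes the block fit gave 30 of 7112 genes, 19 of them also called over 3 cultures. Tied genes lowered the typical residual spread (prior SD 0.103 with them, 0.110 without) and raised the prior degrees of freedom (8.97 against 5.70). After quantile normalization the block fit gave 514 (264 higher, 250 lower) and after median centring 188 (92 and 96). The fit over 3 cultures gave 516 without culture 1, 249 without culture 2 and 115 without culture 3. The 19 genes alike in 3 cultures became 239 at 1.2-fold, 1 at 2-fold, and 32 to 52 with 1 culture left out. The correlation of culture 1 with cultures 2 and 3, 0.504, was 0.454 with no filter, 0.624 at the 50th percentile, 0.523 with the 40th percentile floor, and 0.381 to 0.504 with 1 culture left out. The 8 gene lists past the test became 0 with an estimated correlation and 0 with fry, and 13 over 3 cultures without culture 2. They ranged from 7 to 13 with 1 array left out. The cause of the other moves was not tested.

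ESR1 had no value at the 50th percentile filter. Leaving out 1 array leaves a lone array in its arm, assumed to vary like the other, and breaks the pairing, so the difference then also holds the difference between cultures 2 and 3. The ESR1 difference then ran from -0.46 to 0.21. Of the 121 other genes of the rule and 3 proteases named later, 52 turned in sign with some array left out. Their ranges were ACTA2 -0.26 to 1.36, ACTG2 -1.56 to 2.88, ADH1B -1.76 to 0.22, BMP2 -1.16 to 0.87, BMP4 -1.30 to 0.57, CCL8 -0.76 to 0.28, CXCL1 -0.56 to 0.20, CYP1B1 -1.06 to 0.37, DDB2 -0.0984 to 0.60, DHRS3 -0.79 to 0.21, DNAJB9 -1.07 to 0.24, DUSP1 -0.98 to 0.37 and ELF3 -0.0291 to 0.32. Further ranges were ESAM -0.41 to 0.0915, FOXO1 -0.88 to 0.53, GNLY -0.0754 to 0.31, HAND2 -0.34 to 0.0916, HMGCS1 -0.00898 to 0.61, HSD11B1 -1.60 to 0.74, HSD17B2 -1.53 to 0.86, ID2 -0.0724 to 0.85, IGFBP1 -3.23 to 2.52, IGFBP3 -1.37 to 0.28, IL1R1 -2.19 to 0.25, IL33 -0.15 to 0.93 and INHBA -0.70 to 0.0675. Further ranges were IRF9 -0.0908 to 0.79, JUP -1.06 to 0.0673, KDR -0.37 to 0.68, KRT8 -0.26 to 0.62, LEF1 -0.14 to 0.60, MMP1 -0.19 to 1.31, MVD -0.51 to 0.0357, MX1 -0.46 to 0.92, NCAM1 -0.38 to 0.59, NR3C1 -0.0214 to 0.37, NR4A2 -1.32 to 0.79, PGR -0.35 to 0.0560, PPIA -0.0361 to 0.48 and PRL -0.87 to 0.48. Further ranges were RDH10 -1.60 to 0.62, RORB -1.59 to 0.47, SOD2 -1.34 to 0.48, SPP1 -0.95 to 0.41, TBP -0.0408 to 0.57, TEK -0.99 to 0.35, TFRC -1.19 to 0.58, TIE1 -0.45 to 0.0402, TNC -0.42 to 1.83, TP53I3 -0.0592 to 0.31, VEGFA -1.21 to 0.22 and WNT4 -1.10 to 0.33. Of the 70 genes of the rule that kept their sign, 54 moved by over 1.5 times, among them MET (0.29 to 2.12), TNFSF4 (0.12 to 2.16), RAB27B (0.0915 to 1.80), SYT1 (0.0434 to 1.47) and CDC20 (0.24 to 1.57). Under the other settings 879 of the 967 values of these genes kept direction and side of the threshold, 86 passed it, and 2 turned. The comparison is with the fit without the block, where no gene passed, so keeping the side means not passing. The 86 came from the fits with a block. Single calls of the block fit were not followed through the filter, probe and rescaling settings. The 2 that turned did so over 3 cultures: KDR went from 0.16 to -0.0260 and NCAM1 from 0.10 to -0.0431, as culture 1 differed in sign for both.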

Other observations

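The tests of the tied values in culture 3, the test of the mitosis genes in cultures 1 and 2, and the count of sign patterns were chosen after the results were seen.

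Several genes of other groups also differed in siESR1 cells. CLDN1, a tight junction protein, had the largest mean difference of the named genes: it rose by 1.73 (3.32-fold, SE 0.13, adjusted p = 9.9e-04 in the block fit), with differences of 1.48 and 1.99 in cultures 2 and 3. It was not compared in culture 1. CLDN11, of the same family, fell by 0.62 (adjusted p = 0.020) but differed by 0.04 in culture 1 and did not pass over 3 cultures (adjusted p = 0.14). CNN1, the smooth muscle protein calponin, rose by 0.93 (1.90-fold, adjusted p = 0.0049), and differed by 0.50 in culture 1. ACTA2, smooth muscle actin, differed by 0.26, 0.92 and 0.17 in cultures 1, 2 and 3 (adjusted p = 0.14 in the block fit). VEGFC, a lymphatic growth factor, rose by 0.65 (1.57-fold, adjusted p = 0.027). IFI44L, an interferon-induced gene, rose by 1.08 (2.12-fold, adjusted p = 0.019), and CD68, a lysosomal protein used as a macrophage marker, fell by 0.79 (1.73-fold, adjusted p = 0.028). Neither was compared in culture 1, where IFI44L (4.16 with siControl and 4.48 with siESR1) fell under the filter and CD68 had no probe that could be used. In the block fit without the tied genes CLDN1 and CNN1 passed, while CLDN11, VEGFC, IFI44L and CD68 did not (adjusted p = 0.064, 0.074, 0.070 and 0.076).

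In the fit over 3 cultures, HSD17B2, an enzyme that inactivates estradiol, differed by -0.53, -0.17 and -0.50 in cultures 1, 2 and 3 (adjusted p = 0.047), and ID2, an inhibitor of differentiation factors, by 0.29, 0.51 and 0.27 (adjusted p = 0.043). The cytokine IL33 differed by 1.28, 0.63 and 0.15 and missed the threshold (adjusted p = 0.075). HSD11B1, which activates glucocorticoids, differed by -0.40 and -0.86 in cultures 1 and 2 and was tied in culture 3 (adjusted p = 0.16).

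The mitosis genes were higher with siESR1 in all 3 cultures. The tables argue against 3 technical explanations. Tied values in culture 3 cannot account for the shift, since 0 of the 24 members tested were tied. The list's percentile of 100 among matched random lists in cultures 1 and 2 is therefore no further test of ties. Ties did bear on the calls, 16 of 24 in the block fit and 4 of 24 without the tied genes. Scaling of the arrays cannot account for the shift either: the median was 0.638 or more after both rescalings. Nor did a few genes carry it, since 100% of members were above 0 in all 3 cultures. The members cannot be taken as independent (estimated correlation 0.90 in the fit without the block), so neither the percentile nor this share measures chance. A lower level of ESR1, an effect of the siRNA on other genes and a difference in cell density between wells stay open and were not tested.

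Identical values in the arrays of culture 3 were more frequent where a value recurred within the array: 79.7% of clusters with a recurring siControl value were tied against 24.1% of the others, a gap of 55.5 percentage points. Ties were also more frequent at low signal: over 10 equal classes of signal the share was between 60.2% and 68.5% in the 6 dimmest and then fell step by step to 16.0% in the brightest. The 16.0% in the brightest class, against 0.0571% of all clusters in culture 2, argues against low signal as the only cause. A candidate explanation, not tested, is a processing step that replaced signals by shared values in this pair. Shared values alone do not account for the 24.1% tied among clusters whose siControl value did not recur. The design gives no biological explanation to test.

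A further hypothesis was that siESR1 may shift cells toward the less decidualized of the 2 other cultures. With siControl, culture 2 held more IGFBP1, PRL (2.56-fold), FOXO1 (2.66-fold) and WNT4 (2.69-fold) than culture 3, and 18 of 23 decidualization genes were higher in it. Across 8982 genes the culture 1 difference correlated with culture 2 minus culture 3 at r = -0.163 (rho = -0.128), and at -0.148 without the mitosis, replication and decidualization lists. The sign is that of the hypothesis and the size is small. Other differences between cultures 2 and 3 stay open.

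For the fit over 3 cultures, the real signs gave 328 genes and the highest of the other sign patterns gave 0, so 1 of the 4 patterns gave as many. The 4 patterns are too few for a share under 0.05.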
